A study of Rattus norvegicus with 4 samples.

How the data were processed

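Total RNA of laser-captured rat vestibular ganglion neurons was hybridised to 1-colour (Cy5) arrays, 2 for cells labelled calretinin-positive and 2 for cells labelled calretinin-negative, per the labels. The deposited values are probe intensities on a linear scale, in the authors' processed value table; the scanner, background correction and normalization are not given in the sources used here. The array medians were all near 0.99, so the values appear to be scaled to each array's median, while their centring by gene and the processing behind them stay unknown. Groups and replicate numbers came from the sample titles.

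Of 35126 probes, 9 were missing on every array. Entries of -9999 were read as missing (between 1 and 30 per array besides those), and zero, negative (532 to 776 per array) or missing values were set to the 1st percentile of the array's positive values before log2. The array medians lay within 5% of each other, so no further normalization was applied. Probes whose mean log2 value lay below the 40th percentile, at an intensity of 0.456, were left out, which left 21070; a group below that limit is given by its level, with no fold. Control probes could not be told from genes by a column of the table and stayed in the test. The probe of Sdha, a named gene, is 1 of the repeated probes used below as controls.

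Probes were named from the platform annotation given with the series, with symbols updated by gene ID through a rat gene table: 16677 probes had 1 symbol, 163 several and 18286 none, and 16649 of the first had their gene ID in the table. Probes with several symbols were not named, and no coordinates are given because no genome build is named for the probes. The design fixed before the data were examined assumed that each name belonged to the value at its ID. This was checked with control probes repeated on the array, with the levels of abundant gene families and with pairs of probes for 1 gene, and did not hold in the late part, from the fifth control row on; so only names of IDs up to the fourth control row were used, a departure from that design. The 7218 single-symbol probes of the late part were read only with names moved by 5 table rows, as an alternative, and 2010 between the parts were not named.

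Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. A gene with several probes was represented by the brightest. Of 20 gene lists fixed before the data were examined, those with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Named genes followed a rule fixed at the same time: Calb2, Calb1, Pvalb and Prph; the 10 higher and 10 lower genes with the smallest p among those with an adjusted p under 0.05, an absolute log2 change of at least 1 and groups that did not overlap; and the 2 members with the smallest p of each list, or 3 for the nicotinic, muscarinic and peptide lists. Apoe, Calm2 and Tacr1 were named in addition, after their values were seen. Means and SDs are on the linear scale and log2 changes are positive minus negative.

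On simulated arrays with the real probes' means and spreads (21070 probes, 200 changed), limma recovered 19.4% of changes of 0.5 on the log2 scale, 55.2% of changes of 1 and 89.4% of changes of 2, with 3 of 112 calls among unchanged probes; camera called the 1 shifted set and 0 of the others. Far fewer probes were changed there than were called in the data (13530), so these shares need not hold for the data. The simulated probes varied independently, so the preset correlation of camera was not put to a test. Alternatives were replicate number as a block, quantile and cyclic loess normalization, other filters on dim probes, raised low values, other variance priors, a threshold of 0.10, a test of each probe on its own spread, other list tests, means over probes and leaving out each array. Chosen after the data were seen were the moved names, all names as deposited and missing values left missing. Lists of oligodendrocyte, astrocyte, and meningeal and mesothelial genes were also written after the main comparison was seen and before the changes of their members were looked at. Figures were drawn with matplotlib 3.10.9.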

Results

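Vestibular ganglion neurons of the rat were collected by laser capture microdissection under immunofluorescence for calretinin, a calcium-binding protein, and their pooled total RNA was profiled on 1-colour (Cy5) expression arrays. Calretinin-positive cells are the afferents that end as calyces on hair cells, and calretinin-negative cells the dimorphic and bouton afferents, per the series' design text. Each of the 2 groups had 2 arrays, grouped by their titles, because the descriptions of the negative samples repeat the wording for positive cells. The groups are therefore called libraries labelled positive and libraries labelled negative. Each array carried 35126 probes, and the array medians lay near 0.99 on the deposited linear scale. The number of arrays limits the precision of every value, and the number of animals behind each pool is not given in the sources used here.

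The names of the probes could be used for part of the table only. Probe IDs number the array by row and column, and control probes in the first and second control rows had nearly the levels of the same probes in the later control rows of the early part (r = 0.999 across 28 pairs of probes, which are not independent replicates). Control probes of the last control rows of the early part repeated in the later control rows correlated at r = 0.148 with the values listed at their own IDs and at r = 0.941 with the values 5 table rows later (54 pairs). Genes are therefore named from the early part of the array, up to the fourth control row, which held 7449 probes with 1 symbol, and names moved by 5 table rows in the late part, from the fifth control row on, are given as an alternative, chosen after the data were seen. Counts of probes do not depend on names and cover the whole array.

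**Figure D1:**
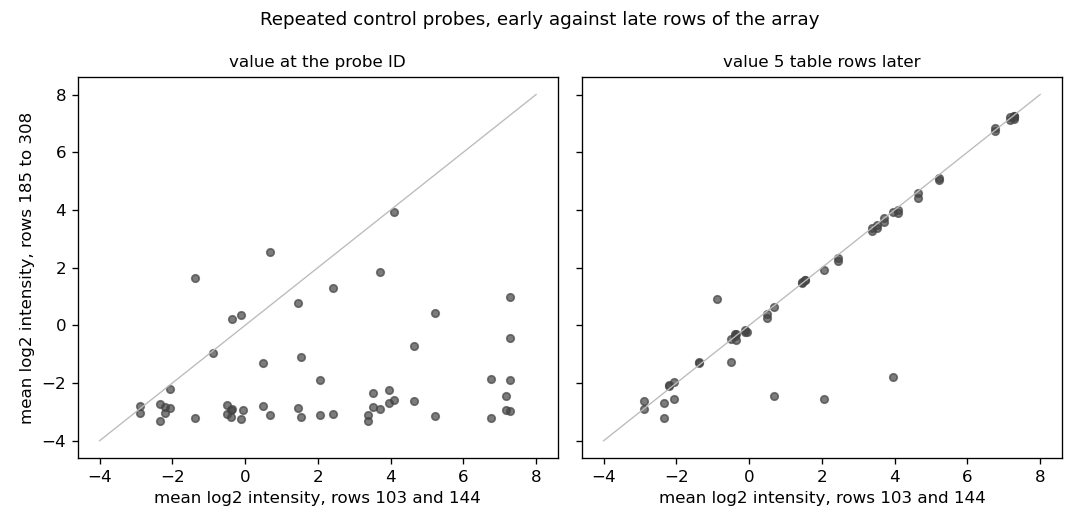
Mean log2 intensity over the 4 arrays of control probes in the last control rows of the early part (x axis) against the same probes in the later control rows (y axis), with the value listed at the probe ID (left) and the value 5 table rows later (right); each point is 1 of 54 pairs and the grey line marks equality. The correlation was 0.148 on the left and 0.941 on the right.

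The series compared the transcripts of calretinin-positive with those of calretinin-negative afferents. The genes with the smallest p that were lower in the libraries labelled positive included Mog and Mobp, which encode proteins of central nervous system myelin, and Gfap, an intermediate filament protein of astrocytes and some other glia. Mog had an intensity of 1.0001 ± 0.0209 (SD, n = 2) in the libraries labelled positive and 42.9 ± 1.25 in those labelled negative. Mobp had 1.90 ± 0.158 and 76.6 ± 1.25, Gfap 1.04 ± 0.0739 and 44.5 ± 2.41, and Tf, the iron carrier transferrin, 8.87 ± 0.222 and 185.2 ± 8.57. Lgi4 (log2 change -4.82), which encodes a secreted protein of peripheral glia needed for myelination, Mmd2 (-3.90), Pias1 (-4.03), Pdlim3 (-3.82), Map7 (-3.57) and Sphkap (-3.78) completed the 10 lower genes.

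Among the 10 genes higher in the libraries labelled positive, Rarres1 had an intensity of 76.7 ± 0.578 (SD, n = 2) against 9.19 ± 0.0128, and Shisa3 had 114 ± 7.99 against 20.3 ± 0.722. Cxcl1, a chemokine, had 13.3 ± 0.358 against 0.649 ± 0.0239, and Itga11, a collagen-binding integrin subunit, 23.6 ± 1.98 against 1.04 ± 0.108. Upk1b, a tetraspanin of the urothelium, was 6.22-fold higher, Moxd1 7.21-fold, Anxa8 7.24-fold, Calml4 7.38-fold, Ms4a8 7.37-fold and the organic anion transporter gene Slco4a1 5.64-fold. For these 20 genes the largest adjusted p was 1.46e-08 (limma, Benjamini-Hochberg).

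**Figure D2:**
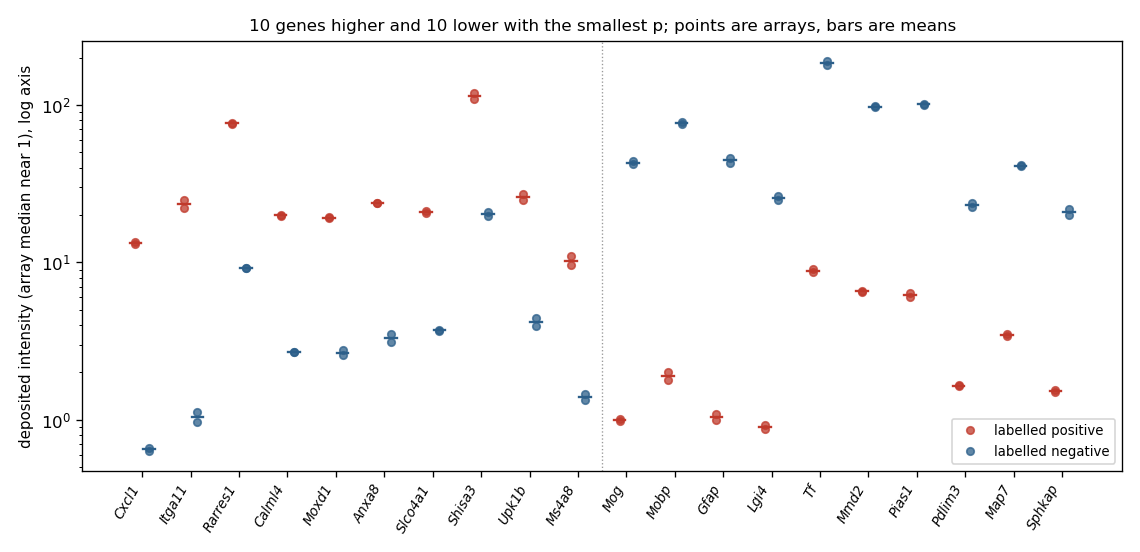
Deposited intensity (y axis, log scale, array median near 1) of the 10 genes higher and the 10 genes lower in the libraries labelled positive with the smallest p (x axis); each point is 1 array and each bar the mean of 2 arrays. Mog lies near 1.0 in the libraries labelled positive and near 42.9 in those labelled negative, and Rarres1 near 76.7 and 9.19.

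Over all 21070 probes tested, 13530 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 8564 higher and 4966 lower in the libraries labelled positive. Of these, 3234 differed at least 2-fold, 1744 higher and 1490 lower, and 791 at least 4-fold, 304 higher and 487 lower. The share of calls that were higher, 63.3%, was 53.5% after quantile and 49.6% after cyclic loess normalization, and the median log2 change of all tested probes, 0.11, became 0.01 and -0.01, so small changes have no settled direction. Before such normalization the median log2 change grew with the level, from -0.00176 for probes with a mean log2 below 0 to 0.234 above 4. The shift thus lay mostly in brighter probes. The 2 arrays of a group correlated at r = 0.9896 (positive) and 0.994 (negative) across tested probes, against 0.925 to 0.928 between groups. Nothing in the labels says that replicates came from separate animals or pools, so the p-values measure only the spread between arrays, which may be technical. A permutation of 2 against 2 arrays cannot give a p below 0.333, and a test of each probe on its own spread called 7082 probes.

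Calretinin was used to choose the cells, so its transcript, Calb2, checks the labels and is no finding. The value listed at its probe ID, which lies in the late part, was 6.01 ± 0.121 (SD, n = 2) in the libraries labelled positive and 12.7 ± 0.489 in those labelled negative, a log2 change of -1.08 that goes against the titles (adjusted p = 9.09e-07, limma, Benjamini-Hochberg). At the value 5 table rows later it was 309 ± 26.0 and 134 ± 6.67, a log2 change of 1.21 that goes with them (adjusted p = 1.79e-06, limma, Benjamini-Hochberg). The repeated control probes speak against reading late values at their own IDs, so the first value is not taken as the level of Calb2. The reading they bear out goes with the titles in direction. On that reading Calb2 was also abundant in the libraries labelled negative (134, where the 90th percentile of those arrays was 25.7 and 25.6). The check therefore does not show that these libraries lacked calretinin transcript. The pairing of names and values was examined only after the first value was seen. Parvalbumin, Pvalb, had 137 ± 13.6 and 133 ± 3.21 with the moved names (log2 change 0.04, adjusted p = 0.691, limma, Benjamini-Hochberg). Calb1 has its probe between the parts and is not read here. Prph, which encodes peripherin, an intermediate filament protein of small-calibre and bouton afferents, lies in the early part and had 54.6 ± 0.605 and 110 ± 2.09, a log2 change of -1.01 ± 0.07 (SE; adjusted p = 1.24e-06, limma, Benjamini-Hochberg).

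Gene lists were fixed before the data were examined. Of 10 tested Schwann cell and satellite glia markers 7 fell in the libraries labelled positive, 1 rose and 2 did not pass, and Mbp, a myelin protein gene, had 1.55 ± 0.0163 (SD, n = 2) against 13.4 ± 0.0241. Apoe was the marker that rose, by a log2 change of 0.78. The list was lower than other genes with camera (adjusted p = 0.000726, Benjamini-Hochberg) and not with an estimated correlation (adjusted p = 0.382). The latter has only 2 residual degrees of freedom here, so hardly any list could pass it. All 3 tested endothelial and mural markers fell, among them Esam (1.13 against 4.03) and Tagln (2.67 against 6.84). Of 6 blood and immune markers 3 fell and 2 rose; Csf1r, a macrophage receptor gene, had 50.2 against 115 and the erythroid gene Alas2 6.19 against 15.7; with either normalization 1 rose. Of 7 fibroblast markers 3 rose and 1 fell, with Ogn at 117 against 55.1 and Dcn at 8.48 against 16.5; after quantile or loess normalization 2 fell. Of 2 hair cell markers Ush1c fell by 0.41 on the log2 scale and Otof had 4.47 against 4.89, and both fell with loess normalization.

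Of 6 neuron markers 4 rose and 2 did not pass, with Nefh, the heavy neurofilament subunit gene, at 3.87 ± 0.255 (SD, n = 2) against 1.26 ± 0.157 and Nefm at 102 ± 1.06 against 68.3 ± 0.848; after loess normalization 1 fell. Of 11 axonal cytoskeleton genes 5 rose, 2 fell and 4 did not pass, with quantile normalization 3 rose and 2 fell, and with loess 3 rose and 3 fell. Of 11 synaptic release genes 6 rose and none fell, among them Nsf (6.26 against 2.21) and the vesicular glutamate transporter gene Slc17a7 (2.06 against 0.717). With either normalization 5 of them rose. With the moved names 1 release gene rose at least 2-fold, Slc17a7 (log2 change 1.53), so a brighter probe of Nsf did not show a rise of that size. Neither list passed camera (adjusted p = 0.520 for the neuron markers and 0.236 for the release genes, Benjamini-Hochberg).

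Genes of transmitter signalling, named in the series title as efferent and afferent interaction, included members that fell in the libraries labelled positive, where markers of glia (Gfap, log2 change -5.42) and endothelium (Esam, -1.83) fell too. Of 8 peptide, opioid and purinergic genes 4 fell and 4 did not pass. The enkephalin precursor gene Penk had 0.556 ± 0.142 (SD, n = 2) against 5.32 ± 0.335, the nucleotide receptor genes P2ry6 1.66 ± 0.196 against 10.5 ± 0.240 and P2ry2 1.29 ± 0.0801 against 2.73 ± 0.251, and Tacr1 also fell. The list passed camera (adjusted p = 0.0197, Benjamini-Hochberg) but not with an estimated correlation (adjusted p = 0.382). Of 5 GABA and glycine receptor genes 3 fell, 4 with quantile and 5 with loess normalization, with Gabrb1 at 1.04 against 5.06. Gabra6 was below the dim-probe limit in the libraries labelled positive, with 0.159 against 2.49. That list passed camera (adjusted p = 0.0188, Benjamini-Hochberg), not with an estimated correlation (adjusted p = 0.382), not without either negative array and not with the moved names (adjusted p = 0.213). Of the nicotinic receptor genes 2 were tested: Chrna3 rose from 1.83 ± 0.0268 to 4.21 ± 0.0569, and Chrnb2 had 1.38 and 1.37. Lynx1, a modulator of nicotinic receptors, had 145.9 against 120.9, a log2 change of 0.27 that became -0.01 with quantile or loess normalization. Of 5 glutamate receptor genes 3 rose and 1 fell, and with either normalization 2 rose and 2 fell. Gria3 had 73.5 against 43.6, and Grin2b, below the dim-probe limit in the libraries labelled positive, 0.159 against 2.45, with no call under a robust variance prior (adjusted p = 0.0795, limma, Benjamini-Hochberg).

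Of 6 calcium-binding protein genes 5 fell and 1 rose, with S100a4 at 3.28 ± 0.0972 (SD, n = 2) against 20.2 ± 0.225 and S100b, also a glial marker, at 3.59 ± 0.370 against 8.69 ± 0.204. Calm2, the member that rose, did not pass with quantile or loess normalization. The list passed camera (adjusted p = 0.00395, Benjamini-Hochberg), not with an estimated correlation (adjusted p = 0.382) and not with the moved names (adjusted p = 0.103). With the moved names it also held Calb2, which was used to choose the cells. Among 11 potassium and HCN channel genes 4 rose and 1 fell, with Kcnma1, a calcium-activated potassium channel gene, at 3.14 against 1.29 and Kcna6 at 0.618 against 2.11. With quantile normalization 4 rose and 2 fell, and with loess 3 rose and 2 fell. Of 9 sodium and calcium channel genes 2 fell, Cacna2d1 (0.952 against 3.79) and Cacnb2 (0.583 against 1.09), and 7 did not pass. With the moved names 6 of 18 rose and 5 fell. Of 9 neurotrophic genes 5 fell, among them the receptor genes Ntrk2 (9.18 against 19.9) and Gfra1 (0.636 against 1.47). The glial markers Gfap (log2 change -5.42) and Mbp (-3.11) fell in the same libraries as these channel and neurotrophic genes.

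Of 12 oxidative phosphorylation genes 10 rose and 1 fell, with Sdha at 19.0 against 12.7 and Ndufa1 at 176 against 122. However, 3 of the 12 rose with either normalization, and 1 fell with quantile and 2 with loess. The Sdha probe was 1 of the control probes repeated on the array, with a mean log2 level of 3.96. Of its late repeats, read 5 table rows later, 1 had 3.91 and another -1.80. Of 9 immediate early and heat shock genes 5 rose and 2 fell, with Gadd45a at 9.02 against 4.12 and Egr1 at 16.9 against 9.76. With quantile normalization 4 rose and 1 fell, and with loess 5 rose and 3 fell. Of 4 ribosomal protein genes Rpl6 rose (1.79 against 0.721) and 3 did not pass, Rps24 among them (7.27 against 8.15). With either normalization these 3 fell. With the moved names the largest log2 change in this list was 0.446, so a brighter probe of Rpl6 did not show its rise. Of the 20 lists, 15 had at least 5 tested genes, 4 passed camera and 0 passed with an estimated correlation. With 2 residual degrees of freedom that 0 was close to fixed in advance and decides nothing about the lists. With no filter on dim probes, or with a stricter one, the 2 lists that passed camera were the glial and the calcium-binding list. Adjusted over the list alone, the number of genes called was the same as over all probes in 19 lists and was 5 in place of 4 in the fibroblast list.

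**Figure D3:**
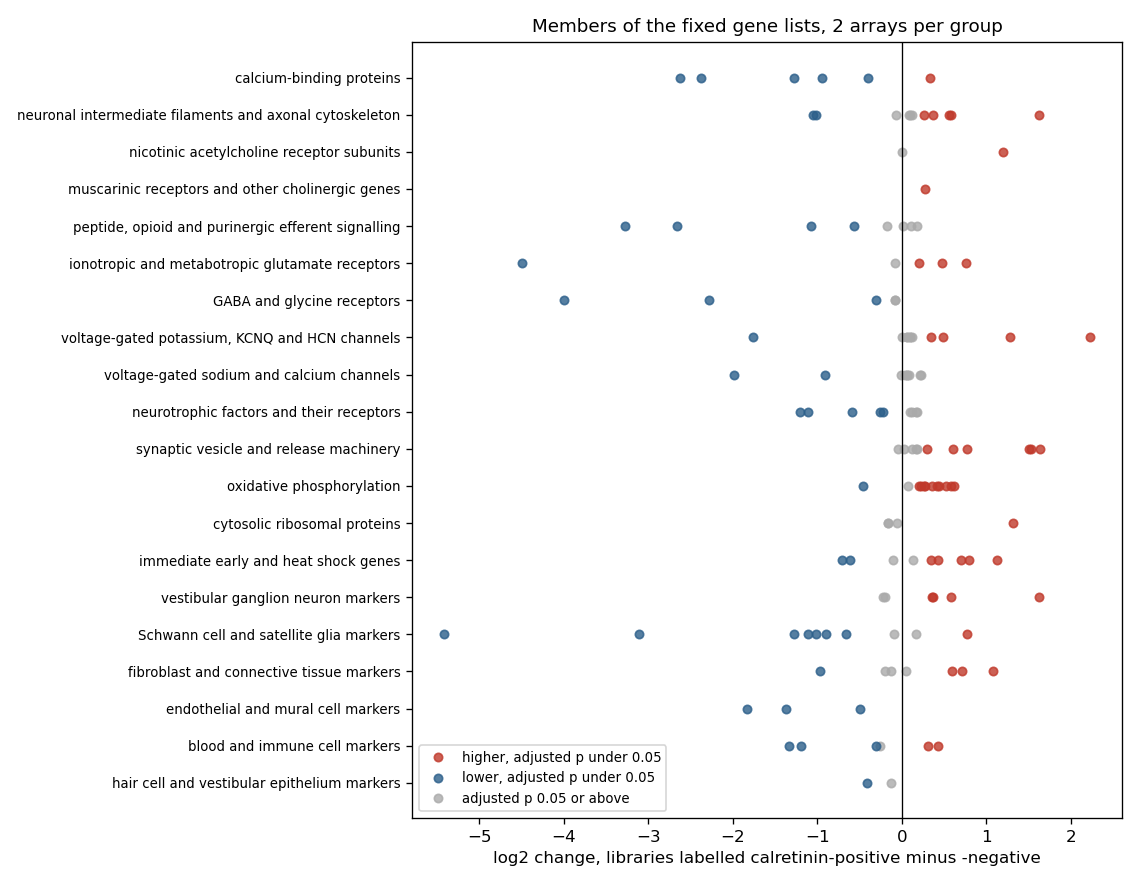
Log2 change between libraries labelled positive and negative (x axis, positive minus negative) of each tested member of the 20 fixed gene lists (y axis), from 2 arrays per group; red and blue points passed an adjusted p of 0.05 (limma, Benjamini-Hochberg) and grey points did not. The markers of Schwann cells and satellite glia hold 7 blue points and 1 red.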

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

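The moved names, all names as deposited and missing values left missing were chosen after the data were seen; the other alternatives were planned. With no filter on dim probes 4886 probes were called at least 2-fold different, 2427 of them lower, and 2 lists passed camera; with probes below the 60th percentile left out, which tests fewer probes, 3153 were lower, 1555 at least 2-fold different (883 higher, 672 lower) and 2 lists passed. A test of each probe on its own spread called 7082 probes, 4492 higher and 2590 lower. Of the lists, 0 passed with a correlation estimated from the data in camera, which leaves 2 residual degrees of freedom and so hardly lets a list pass. With fry in place of camera, which does not compare a list with other genes, 13 passed, and with all names as deposited 2 did. The log2 change at the ID of Calb2, -1.08, was 1.21 with names of the late part moved by 5 rows, the reading the control probes bear out, and that of Lynx1, 0.27, was -0.0116 with quantile and -0.00622 with cyclic loess normalization. Except where the alternative's own construction shows it, the cause was not tested.

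The other settings kept the number of probes called within 1.5 times of 13530. Leaving out 1 array at a time gave 12382 to 12916 calls and 3 to 4 lists; the lone array is then assumed to vary like the other group. Over 14 settings and the 58 genes followed through the settings, 791 of 798 values kept their side of the threshold and, where called, their direction. Of the others, 1 lost its call with its direction kept (Grin2b, with the robust prior) and 4 gained one (Rps24 in 3 settings, Otof in 1). The remaining 2, Lynx1 with quantile and with loess normalization, lost their call and changed sign. These genes were chosen by small p in the same arrays, so their stability says little about calls in general. Genes that a setting left untested are not counted, and 48 of the 58 were tested with probes below the 60th percentile left out. Apoe, Calm2 and Tacr1 are not among the 58; Calm2 lost its call with quantile and with loess normalization. The replicate block gave 13711 calls and 4 lists; same-numbered arrays did not deviate together (r = 0.000316 across 21070 probes), so the numbers are not taken to pair the arrays. The number of arrays limits the values. The replicate SD (positive and negative) was 0.364 and 0.322 for probes with a mean log2 below 0, 0.205 and 0.115 from 0 to 2, 0.273 and 0.127 from 2 to 4, and 0.0866 and 0.0802 above 4.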

Other observations

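With names moved by 5 rows in the late part of the array, further genes could be read, as an alternative reading. Of 9 endothelial and mural markers 8 fell in the libraries labelled positive and 1 did not pass (camera adjusted p = 4.97e-05, Benjamini-Hochberg; adjusted p = 0.397 with an estimated correlation), and of 13 glial markers 10 fell and 1 rose. Of 6 hair cell markers 5 fell (camera adjusted p = 0.00393; adjusted p = 0.433 with an estimated correlation) and of 12 blood and immune markers 7 fell and 4 rose. Of 5 nicotinic receptor subunit genes 3 rose and 0 fell (camera adjusted p = 0.348). Neuron markers rose in 5 of 8 and fell in 1, and release genes rose in 9 of 15 and fell in 1. Lists that passed with names of the early part and did not here were the calcium-binding list (3 rose and 7 fell, adjusted p = 0.103) and the GABA and glycine receptor list (3 rose and 4 fell, adjusted p = 0.213). The calcium-binding list here held Calb2, which was used to choose the cells, as the member that rose most (log2 change 1.21).

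Of the tests below, those on the row shift, late-row signal, neuronal share, normalization and replicate spread were chosen after the result was seen; the lists of oligodendrocyte, astrocyte and meningeal genes were written after the patterns they bear on were seen, and before the changes of their members were looked at. After the values of the astrocyte and neuronal-share tests were seen, 2 rules were set: members going both ways around 0 decide nothing, and the neuronal-share bound must be passed by more than the standard error (SE). The first pattern is that values in the late part do not match the names of their IDs. Weak late hybridisation is argued against by the medians of all probes, which differed by 0.0928 on the log2 scale between the early and the late part. A displacement of the values by 5 table rows may account for it: control probes correlated at r = 0.941 at that shift and at 0.305 at the next best of 41, and fixed abundant genes of the late part had a mean log2 level of 4.17 there against 0.40 at their own IDs. Pairs of probes for 1 gene, with 1 probe in each part, gave r = 0.37 at the shift and at most 0.07 at other shifts. No biological explanation was tested; 35 probes for a wider set of abundant gene families in the last rows before the fifth control row were also brighter at the shift (mean log2 3.68, against 1.67 at their own IDs), but 13 in the rows before them were brighter at their own IDs than at the shift (2.26 against 0.577) and brightest at another shift, and the exact row of the break stays open.

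The second pattern is the higher level of glial genes in the libraries labelled negative; normalization is argued against, since at least 7 of 10 glial markers fell under quantile and loess normalization. A lower share of neuronal RNA raising all other types alike stays open. The median of the fibroblast list lay 1.01 above that of the glial list, past the bound of 0.5 by less than the SE of the difference of means (0.622). That rule sets medians against an SE of means, and the mean log2 changes were 0.163 (fibroblast) and -1.26 (glial). Of 7 fibroblast markers 3 rose, against this explanation, and 1 fell. Median log2 changes, which go with it, were -1.37 for 3 endothelial and mural, -0.284 for 6 blood and immune and 0.366 for 6 neuron markers. RNA of oligodendrocytes is a possible source: 7 of 8 oligodendrocyte genes, none in the fixed lists, fell in the libraries labelled positive. The median log2 change of the 8 was -1.04 (camera adjusted p = 1.59e-06, 0.105 with an estimated correlation), with Plekhb1 at 6.81 against 38.2 and Enpp6 at 1.27 against 16.1. The most abundant, Septin4, was the 1 that did not pass (133 against 146, groups overlapping). Schwann cell markers, the myelin gene Mbp among them, had already been seen to fall when this list was written. The list was not checked for genes that Schwann cells share, so it cannot tell oligodendrocyte RNA from Schwann cell RNA. For astrocytes the median of 5 genes was 0.19, which met the bound set against them, but 2 rose and 2 fell around 0 (SD 3.35, Aqp4 at 0.473 against 50.1, Gjb6 at 185.04 against 126), so it decides nothing. Whether laser capture of stained neurons left such cells out was not tested, and neither was a difference between the afferent types themselves.

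The third pattern is the level of Upk1b, Moxd1, Rarres1 and other genes in the libraries labelled positive. RNA of meningeal or mesothelial cells could not be told apart from other sources with names of the early part: 8 of 14 genes rose and 3 fell, with a median log2 change of 0.26, between the bounds set before, and the most abundant, Ptgds, had 614 against 486. With the moved names, a reading chosen after the data were seen, 19 of 25 rose and 3 fell (median 0.75, camera adjusted p = 0.0171, 0.187 with an estimated correlation), among them Slc47a1 at 243 against 59.3 and Crabp2 at 117 against 34.5. The astrocyte list with moved names had 5 of 10 lower and 3 higher, and the oligodendrocyte list 10 of 16 lower and 2 higher. Separately, the SD between replicate arrays was 0.901 times that between duplicate spots, which sets single arrays against technical noise and so cannot show whether the arrays of a group carried 1 RNA preparation.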
